A study of Mus musculus with 16 samples.

How the data were processed

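The series holds 16 samples of female mouse ES cells, of which 9 had files used here: 4 CLIP libraries with UV, 3 CTCF ChIP libraries and 2 nuclear RNA-seq libraries. CLIP libraries without UV and ChIP inputs were not analysed here, so no background from them stands beside the values. Groups and replicate numbers came from the sample titles. Nothing in the labels says that replicates were separate cultures, so the limma p-values measure only the spread between these samples, which may be technical. Fisher exact tests count regions or peaks as independent and the shuffles move peaks, so their p-values do not measure spread between samples. Strain labels differ between assays: CAST/Ei x 129/Sv/Jae for CLIP and RNA-seq, and 129S1/CastEiJ x 129S1 for ChIP.

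Trim Galore 0.3.3, cutadapt 1.0, TopHat2 2.0.8, Novoalign 3.00.03, SAMtools 0.1.18, bedtools 2.17.0 and Cufflinks 2.1.1 were used with build mm9, per the submitters' processing notes, which give no role or order. The peak caller is not given in the sources used here. The deposited peak lists hold a score per peak, which is the authors' own value. It was used to rank peaks within a list, and some score values are also given as listed. The RNA-seq lists deposited by the authors hold a value taken as FPKM, since Cufflinks reports that unit; the files do not name it. Rows that pool several transcripts hold a single FPKM in the deposited files, which appears to be a mean over them, and very short transcripts can have very high values. Neither list held a value of 0, so a region missing from the list of a day was set to 0. The allelic lists carry further columns whose meaning is not given, and these were not used. Every allelic peak was one of the peaks of the full list of its library. Peaks were listed per library, so replicates could be compared by overlap.

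Chromosomes 1 to 19 and X were used. Day 0 and day 3 RNA-seq rows overlapping on one strand were merged into 42917 regions, which stand in for the genes of the planned tests. The FPKM of a region at a day was that of its highest row. Peaks were shared when they overlapped by at least 1 bp. A region was bound at a day when each replicate had at least 1 same-strand peak in it. Overlaps were set against 100 seeded shuffles within transcribed regions, ranked 1-sided. Proportions have exact Clopper-Pearson 95% intervals, and X was compared with autosomes by two-sided Fisher exact tests. Day 3 was compared with day 0 by limma 3.58.1 in R 4.3.3 on log2 of same-strand peak bases per Mb of peak bases in the library plus a pseudocount of 1, for regions with peaks in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold on this scale understates the change of low regions. RNA-seq change was log2 of FPKM plus 1 at day 3 over day 0. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Overlap and limma steps were tested on simulated data: an overlap of 30% was recovered as 30.67%.

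Tests, alternatives and the rule for naming regions were fixed before the data were examined. The rule took, per day, the 12 bound regions of at least 1 kb and FPKM of at least 1 with the most peak bases per kb. With no region past the threshold, it took for the day comparison the 10 per direction with peaks in both libraries of one day and neither of the other. For RNA-seq it took the 10 largest changes per direction with mean FPKM of at least 5 and length of at least 300 bp. Some of each are printed. The X locus, the segments of chromosomes 6 and 8, the window classes, the chromosome shares, and the RNA-seq sets by row length, by length-weighted mean, by single transcripts and by listing at both days were chosen after values were seen. Tests on gene lists, tests per gene of the X-inactivation centre and the search for the CTCF motif needed gene names or an mm9 sequence and were not run. CLIP alleles on X were compared with chromosome 13 in place of all autosomes. Alternatives covered the overlap rule, peak score, shuffle space, FPKM minimum, pseudocount, scaling, a replicate block and leaving out each library.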

Results

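CTCF is a zinc-finger protein that binds DNA at insulators and domain boundaries. The series measured its RNA contacts and its chromosomal sites in female hybrid mouse embryonic stem (ES) cells, with attention to the X chromosome. Cells were studied undifferentiated (day 0) and after 3 days without LIF in suspension (day 3). CLIP recovers RNA crosslinked to a protein by UV light and was done here with anti-FLAG beads, with 2 libraries per day. CTCF ChIP had 2 libraries at day 0 and 1 at day 3, and nuclear RNA-seq had 1 library per day. CLIP lists held 114016 and 213181 peaks at day 0, and 106382 and 165695 at day 3. ChIP lists held 45377 and 76745 peaks at day 0, and 41264 at day 3. The RNA-seq files listed 40668 transcribed regions at day 0 and 28677 at day 3. Read depth is unknown for all of these lists. The RNA-seq rows carry assembly identifiers that the files do not pair with gene names, so regions are given by mm9 position.

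CLIP peaks lay on the transcribed strand. Of peaks in regions transcribed on 1 strand, 98.3% in both day 0 libraries and 98.7% and 98.3% in the day 3 libraries were on the strand of the region. The exact 95% intervals of the 4 libraries spanned 98.2% to 98.7% and cover counting error only. Between 83.4% and 84.7% of the peaks of a library fell in a same-strand transcribed region.

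The 2 day 0 CLIP libraries shared more peaks than shuffled lists did, and so did the 2 day 3 libraries. At day 0, 17.8% of replicate 1 peaks were overlapped by replicate 2, against 2.06% ± 0.0466 (SD over 100 shuffles). At day 3 the share was 11.9%, against 1.78% ± 0.0425. Both ranked above all shuffles (1-sided permutation p = 0.0099 over the shuffles, the smallest they can give). Libraries of different days overlapped about as much as libraries of the same day. The mean fold over shuffles was 8.72 within day 0 and 6.67 within day 3, and ranged from 6.92 to 8.17 between days. With 2 libraries against 2, an exact relabelling test cannot go below p = 0.33, and no test of a difference between days in overlap was made.

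**Figure D1:**
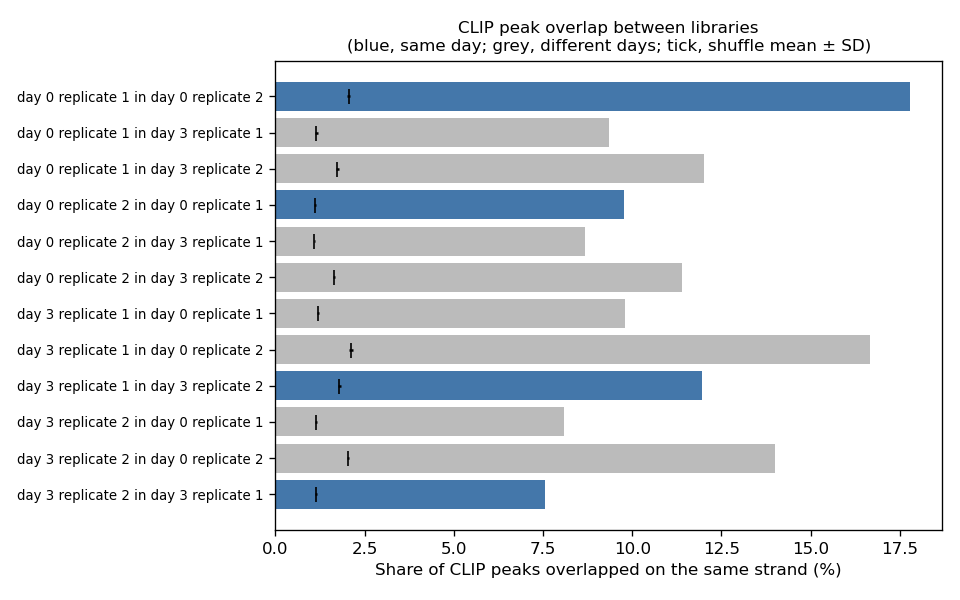
Share of the peaks of each CLIP library overlapped on the same strand by each other library (bars, in %), with the mean and SD of 100 shuffles (ticks). Day 3 replicate 1 peaks were overlapped more by day 0 replicate 2 (16.7%) than by day 3 replicate 2 (11.9%).

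The question of which RNAs carried CLIP peaks was asked per transcribed region. At day 0, 9374 of 42917 regions had a same-strand peak in both replicates, and at day 3, 9019 had; 7682 were bound at both days. Bound regions were long, with a median of 29450 bp against 615 bp for unbound regions at day 0, among those with FPKM of at least 1. The highest density of peak bases at both days was on chromosome 19, 5794634 to 5802671, minus strand, with 718.5 ± 27.0 peak bases per kb at day 0 and 721.6 ± 19.8 at day 3 (SD, n = 2). A neighbouring minus-strand region, chromosome 19, 5824708 to 5845478, had 472.8 ± 11.5 at day 0 and 237.6 ± 89.2 at day 3. A plus-strand region on chromosome 16, 23107358 to 23114522, had 339.3 ± 43.8 and 226.4 ± 20.1. A plus-strand region on chromosome 7, 3217847 to 3219910, had 536.1 ± 93.5 at day 0, when the RNA-seq list did not hold it, and 410.9 ± 74.7 at day 3. These densities were not scaled to the lists, which held 4.92 and 8.30 Mb of peaks at day 0 and 4.71 and 6.80 Mb at day 3. Their differences between days may in part reflect the size of the lists. Over regions of any length, peak density and nuclear FPKM had a Spearman rho of 0.0423 at day 0 and 0.00124 at day 3. Among regions of at least 1 kb it was 0.328 and 0.292. These are correlations across regions, which are not independent replicates. They include very high FPKM values of short or pooled rows, which are not read as RNA levels below.

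X-linked regions were bound more often than autosomal ones at both days. At day 0, 371 of 1238 X regions with FPKM of at least 1 were bound (29.97%, exact 95% interval 27.4 to 32.6), against 25.4% of 34130 autosomal regions (odds ratio 1.26, two-sided Fisher exact p = 0.000337). At day 3, 334 of 813 X regions were bound (41.1%, 37.7 to 44.6), against 34.2% of 23819 (odds ratio 1.34, Fisher exact p = 6.76e-05). X ranked 1 of 20 chromosomes in reproducible peaks per expressed region at both days. Per transcribed Mb it ranked 1 at day 0 (50.6 peaks) and 2 at day 3 (28.3, against 31.1 on chromosome 12). In a logistic model with log2 FPKM and log2 length of the region, the odds ratio was 1.99 at day 0 and 1.86 at day 3. The FPKM in that model includes very high values of short or pooled rows, which are not read as RNA levels below. The ratio of the day 3 to the day 0 Fisher odds ratio was 1.07 and did not pass a test on the log scale over regions (two-sided normal approximation, n = 1238 and 813 X regions, p = 0.507). That test took the days as independent, though they share regions and 7682 were bound at both days. It therefore cannot settle whether the odds ratio changed. Regions are not replicates, so these tests describe these libraries. With a minimum FPKM of 0.1 the day 3 odds ratio was 1.14 and no longer passed (Fisher exact p = 0.0518).

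No region differed between days in CLIP peak bases. limma with Benjamini-Hochberg adjustment tested 12325 regions and called 0 at an adjusted p of 0.05, with a smallest adjusted p of 0.662. At an unadjusted p under 0.05 there were 899 regions, where 616 would be expected by chance. Peaks in both libraries of day 0 and neither of day 3 were found in 424 regions, and the reverse in 301. Pairs of libraries from different days alone gave 772 regions for both replicate 2 libraries, 141 for both replicate 1 libraries, and 329 and 372 for the crossed pairs. Regions with peaks at day 0 alone included chromosome 6, 95067002 to 95079712, plus strand (log2 difference -5.77 ± 1.46 SE), chromosome 6, 114232396 to 114267516, plus strand (-5.52 ± 1.45), and chromosome X, 70728983 to 70741272, plus strand (-5.41 ± 1.57). Those with peaks at day 3 alone included chromosome 4, 102431744 to 102543499, plus strand (5.78 ± 1.63), and chromosome 11, 84771288 to 84779546, plus strand (5.54 ± 1.47). Each had a Benjamini-Hochberg adjusted p of 0.662 in limma, so these are values and not calls. In simulated data for this comparison, 25.5% of 200 regions changed by a log2 of 3 were recovered, so changes of that size could be missed. The simulation drew normal values around spreads smoothed over regions, without the lower limit that the pseudocount sets. The recovered share may therefore not hold for these lists.

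An X-linked locus with transcripts on both strands was examined after its values were seen. A plus-strand region at X, 100626856 to 100680296, had 137 ± 39.6 CLIP peaks at day 0 and 69.5 ± 47.4 at day 3 (SD, n = 2). A minus-strand region inside it, X, 100655444 to 100678556, was in the RNA-seq list of day 3 and not in that of day 0. It had 11 CLIP peaks in each day 0 library, and 67 and 13 in the day 3 libraries. The counts on both strands were not scaled to the number of peaks in the library. The log2 ratio of mean peak bases, as a share of each library, was 2.74 on the minus strand and 0.82 without day 3 replicate 1, so the higher value rests on that library. On the plus strand it was -1.13, and -0.74 without the same library. Nuclear FPKM of the plus-strand region was 66.95 at day 0 and 13.14 at day 3, a log2 change of -2.27 with 1 library per day. Among the 200 regions nearest in FPKM, its peak density was at percentile 92 at day 0 and 95 at day 3. The fewer plus-strand peaks at day 3 thus cannot be told apart from lower RNA. Neither region passed limma (Benjamini-Hochberg adjusted p = 0.662 for both). CTCF ChIP peaks shared by all 3 libraries lay inside the plus-strand region, starting at 100635455, 100638255, 100654634, 100663525 and 100672107. A further shared peak, 100678677 to 100680562, started beyond the minus-strand region and ran past the end of the plus-strand region.

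**Figure D2:**
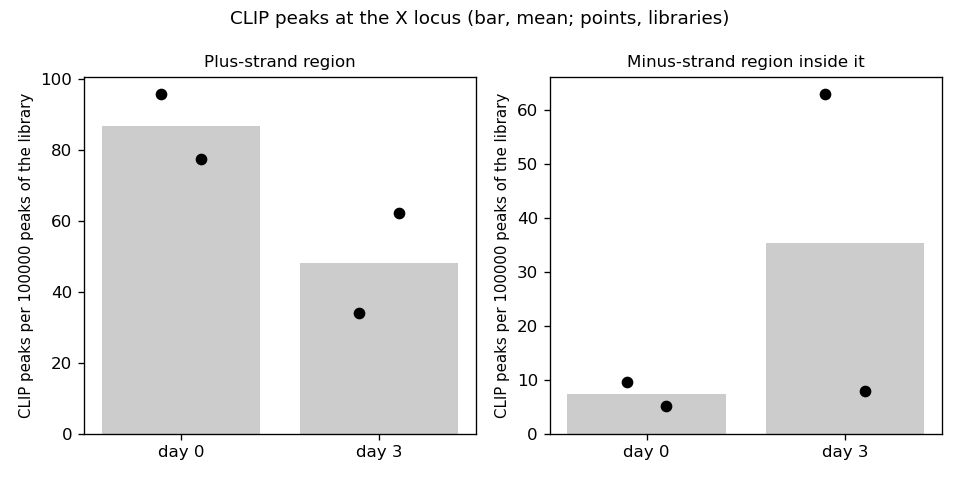
CLIP peaks, scaled to the number of peaks in the library (y axis), in the plus-strand region and in the minus-strand region inside it, at day 0 and day 3; bars are means of 2 libraries and points are libraries. On the minus strand, day 3 replicate 1 stood at 63.0 and day 3 replicate 2 at 7.85.

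Few CLIP peaks lay over CTCF ChIP peaks, though more than in shuffles. At day 0, 1141 of 20286 reproducible CLIP peaks (5.62%, exact 95% interval 5.31 to 5.95) overlapped a ChIP peak found in both replicates, 1.26 times the shuffle mean of 4.47%. At day 3, 651 of 12712 overlapped a peak of the single day 3 ChIP library (5.12%, 4.74 to 5.52), 1.15 times the shuffle mean. The days thus rest on unlike ChIP lists, of 32588 replicated peaks at day 0 and 41264 unreplicated peaks at day 3. Both ranked above all 100 shuffles (1-sided permutation p = 0.0099 over the shuffles, the smallest they can give). With either ChIP library of day 0 alone the day 0 fold was 1.85 (replicate 2 peaks) and 1.07 (replicate 1 peaks), so its size rests on which list is used. On X the fold was 1.83 at day 0 (82 of 1427 peaks) and 1.38 at day 3 (34 of 779 peaks), against 1.23 and 1.15 on autosomes. The day 3 share on X did not rank above all shuffles (1-sided permutation p = 0.0495 over the shuffles). The difference between X and autosomes was not tested. Of the 32588 ChIP peaks of day 0 replicate 2 also found in replicate 1, 2.01% held a reproducible CLIP peak. The ChIP and CLIP samples carry different strain labels, so the 2 assays were not shown to come from one cell line.

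Most CTCF sites of day 3 were present at day 0. Of the 41264 day 3 peaks, 88.1% were overlapped by at least 1 day 0 library, 68.9% by replicate 1 and 86.7% by replicate 2. Between the day 0 replicates, 73.0% of replicate 1 peaks were in replicate 2 and 42.5% of replicate 2 peaks were in replicate 1. Day 3 peaks found in neither day 0 library had a median score, as the authors' lists give it, of 17.1, against 36.9 for those in both. On X, 65.3% of day 3 peaks were in day 0 replicate 1 and 83.1% in replicate 2, against 69.0% and 86.9% on autosomes. Day 3 had 1 library, so no test was made.

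X held a smaller share of features at day 3 in all 3 assays. Its share of CLIP peaks was 5.19% and 5.16% in the day 0 libraries and 4.71% and 4.63% in the day 3 libraries, the lowest log2 change of 20 chromosomes by day means (-0.15). Its share of ChIP peaks changed by -0.15 and its share of transcribed regions of at least 300 bp by -0.09, each the lowest of the 20. Over transcribed regions of any length, the X share was 3.87% at day 0 and 3.58% at day 3, and no rank was computed. By single libraries X ranked 3 and 2 from the lowest for ChIP, and 2 for CLIP day 3 replicate 1 against day 0 replicate 2, where X was at -0.13 and chromosome 16 at -0.15. These ranks were computed after the shares were seen. Some autosomes differed as much between replicates of one day. The log2 gap was 0.175 for CLIP on chromosome 15 at day 3 and 0.256 for ChIP on chromosome 6 at day 0.

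**Figure D3:**
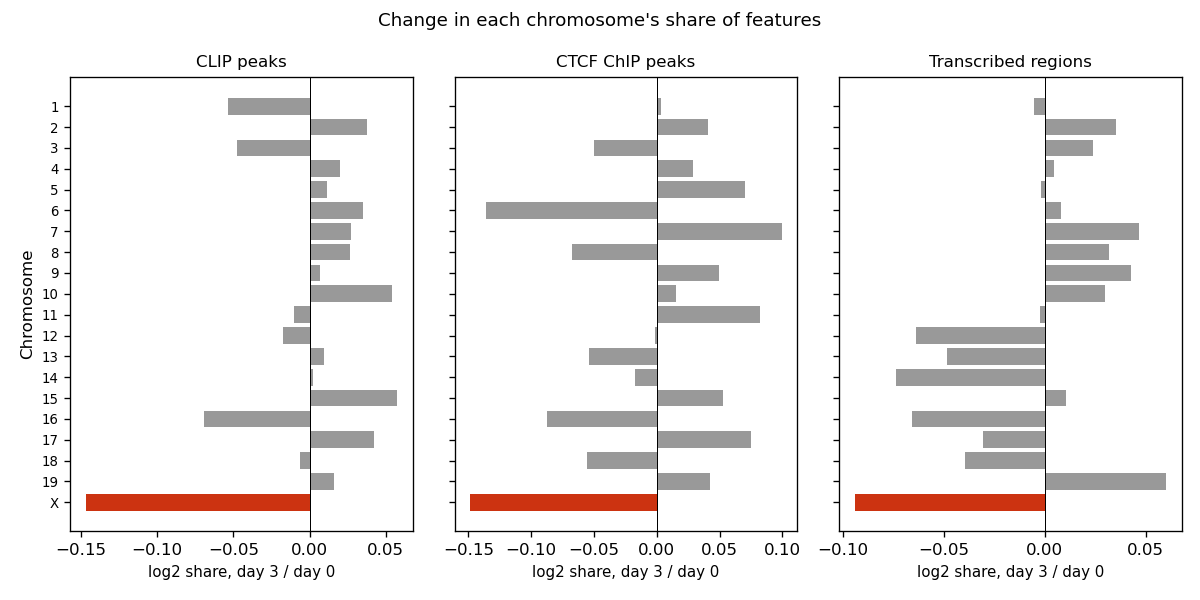
log2 change from day 0 to day 3 in the share of each chromosome (y axis) of CLIP peaks, CTCF ChIP peaks and transcribed regions of at least 300 bp. Shares are means where a day had several libraries. X is in red. X has the lowest value in each panel, at -0.15, -0.15 and -0.09.

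The parental alleles of CTCF ChIP peaks were unevenly spread over chromosomes. The allelic lists name peaks as cas or mus. On X, 244 cas and 254 mus peaks were listed in day 0 replicate 1, 574 and 591 in replicate 2, and 164 and 169 at day 3. The cas share on X was thus 49.0%, 49.3% and 49.2%, against 9.68%, 10.9% and 8.71% on autosomes (odds ratios 8.96, 7.96 and 10.2, two-sided Fisher exact adjusted p = 2.03e-107, 1.28e-225 and 2.85e-80 over 7 libraries). These p-values treat peaks as independent, which neighbouring peaks in one segment are not. The allelic lists held only 27.7%, 39.3% and 22.8% of the X peaks of the 3 libraries. On chromosome 1, nearly all mus, they held 89.6%, 87.4% and 90.1%. The shares on X and on autosomes thus rest on unlike parts of the peaks. On 11 autosomes the cas share was under 5% in all 3 libraries. Chromosome 13 was near even, at 48.7%, 47.6% and 49.4%. Of 268 windows of 10 Mb with at least 10 allelic peaks in each library, 261 fell in one class in all 3: 182 mus (under 15% cas), 68 balanced and 11 with a cas majority (over 65%). The class limits were set after the shares were seen. The 11 cas windows lay at the start of chromosomes 6 and 8, where day 0 replicate 1 had 296 cas and 10 mus peaks (96.7% cas) and 956 cas and 53 mus peaks (94.7%). In replicate 2 these shares were 83.1% and 85.1%.

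**Figure D4:**
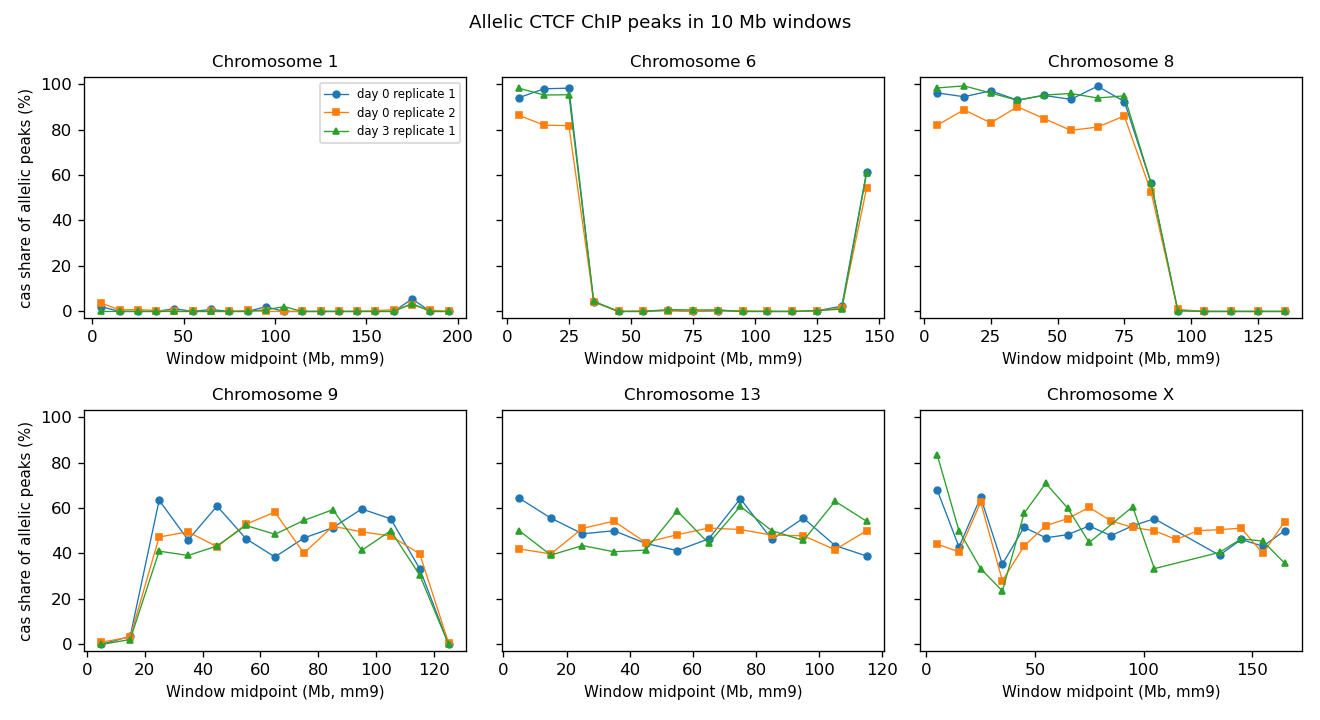
cas share of allelic CTCF ChIP peaks (y axis, in %) along chromosomes 1, 6, 8, 9, 13 and X in 10 Mb windows with at least 10 allelic peaks, for 3 libraries. The 3 libraries change level at the same windows on chromosomes 6, 8 and 9, while windows of chromosome 13 range from 38.9% to 64.3% in day 0 replicate 1, from 39.8% to 54.2% in replicate 2 and from 39.3% to 63.0% at day 3.

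CLIP peaks on X were listed as cas and as mus in near equal numbers. The cas share on X was 47.2% (exact 95% interval 44.6 to 49.9) and 49.5% (47.5 to 51.4) in the day 0 libraries, and 52.4% (49.4 to 55.3) and 48.7% (45.9 to 51.6) in the day 3 libraries. Chromosome 13, used as the autosomal reference because the lists of most libraries cover it and X alone, stood at 47.4%, 48.7%, 49.1% and 47.6%. By library and strand, the allelic lists held 15.0% to 24.9% of X peaks and 26.9% to 38.4% of chromosome 13 peaks. No library passed a two-sided Fisher exact test of X against chromosome 13 (adjusted p = 0.943, 0.697, 0.165 and 0.697). On the plus strand alone the odds ratio was 1.18 in day 0 replicate 2 (Fisher exact p = 0.0264) and 1.35 in day 3 replicate 1 (Fisher exact p = 0.00572), both unadjusted, and on the minus strand alone it was 0.886 and 0.954. Chromosome 13 differed more by strand than X did. In day 3 replicate 1 it was 44.5% cas on plus and 53.9% on minus, against 52.0% and 52.7% on X. In day 0 replicate 2 it was 46.4% and 51.3%, against 50.5% and 48.3% on X. Peaks allelic in 2 libraries carried the same allele in 52.6% to 67.1% of cases on X over the 6 pairs of CLIP libraries, and in 56.9% to 66.7% over the 3 pairs of ChIP libraries. Calls that carry no allele information would also give a share near 50%, so equal use of both alleles on X cannot be read from these shares. On chromosomes 6 and 8 the ChIP share was 98.5% to 99.6%. These chromosomes are largely segments of nearly 1 allele, so this agreement follows from the segments. It does not bear on calls where both alleles are listed. On the near even chromosome 13 the ChIP share was 57.8% to 63.7%.

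Nuclear RNA was compared with 1 library per day and so without a test. Among 20424 regions with mean FPKM of at least 5 and length of at least 300 bp, 5479 had a log2 change of at least 1 and 4081 of at most -1, around a median of 0.30. A region not in the list of a day was set to 0; among the 17153 listed at both days, a set chosen after seeing the data, 4157 were higher and 2132 lower. Centred on the median of 0.30, the counts over all 20424 regions were 4157 higher and 4762 lower. With mean FPKM of at least 1 the counts were 6853 and 11819, and with no FPKM filter 7016 and 12488, with the same minimum length. The balance of higher and lower regions thus depends on scaling and on the filter. Regions set to 0 enter this balance unevenly. Of all 42917 regions, 15687 were listed at day 0 alone and 4166 at day 3 alone. The median was 0.30 on X and on autosomes. The regions with the largest changes under the rule fixed for naming had FPKM of 87783.5 to 695160 at one day, and 11 of those 20 values came from rows under 300 bp. All 1225 rows with FPKM of at least 10000 at day 0, and all 579 at day 3, were under 300 bp or pooled several transcripts. Those values are therefore not read as RNA levels. Among 8353 regions with single-transcript rows of at least 300 bp at both days, a set chosen after this was seen, the median change was 0.39, with 1666 higher and 349 lower. In that set chromosome 5, 35739468 to 35742668, minus strand, went from an FPKM of 0.26 to 35.5, and chromosome 10, 18720716 to 18735519, minus strand, from 0.62 to 43.9. Chromosome 12, 21549138 to 21551238, plus strand, went from 2606 to 11.96, and chromosome 9, 15043449 to 15063837, plus strand, from 18.4 to 0.21.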

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

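The tests on window classes, cas windows, CLIP alleles on chromosomes mus in ChIP, X shares and peak scores within an assay were chosen after the results were seen, while the outcome expected of the score comparison over both assays was written before its result. The allelic CLIP lists of day 0 replicate 1 held 18326 plus-strand peaks on 18 autosomes that the lists of the other libraries do not cover. Of these, 8984 were cas and 9342 mus (49.0%). Chromosome 12 stood apart at 65.8%; the other chromosomes ranged from 43.8% to 50.6%, and without chromosome 12 the share was 47.4%. They enter the weighing of ChIP segments, for 11 chromosomes, and no comparison of days or of X.

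Allelic CTCF ChIP peaks came in segments that were mus, balanced or cas, at the same places in 3 libraries. In windows classed as mus or cas from day 0 replicate 1 alone, at least 82.2% of the peaks of either other library had the allele of the class, which argues against scattered calls from few reads there; in balanced windows, which include some where the class changes, 70.8% of peaks allelic in both other libraries had one allele, and scatter cannot be told apart from allele use. A bias towards mus reads alone is argued against by 11 windows with a cas majority. The ChIP strain label reads as a cross back to 129S1, which may account for mus and balanced segments but would not give a cas majority; this was not tested. Whether the CLIP cells carry the same segments cannot be told apart. CLIP peaks on the 11 nearly mus chromosomes were 49.8% cas in day 0 replicate 1 (46.8% without chromosome 12). However, CLIP calls on X had the same allele in only 52.6% to 67.1% of cases between libraries. On chromosome 13 the share was 59.0% to 69.4%, past a Fisher exact test with Benjamini-Hochberg adjustment in 6 of 6 pairs, so calls repeated there in part.

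The X share of CLIP peaks was lower at day 3. The length of the lists is argued against as the cause on X. Lists of one day that differ in length differed by at most 0.0243 in log2 X share, against -0.15 between days. The gap on X does not measure the spread of chromosome shares in general. On chromosome 15 the 2 day 3 lists differed by 0.175. Lower nuclear RNA on X cannot be told apart from a change in CLIP itself. The X minus autosome median RNA change was -0.0052 (bootstrap 95% interval -0.13 to 0.09 over 1000 resamples). X also had the lowest change in its share of transcribed regions of at least 300 bp. The bound for ruling out lower RNA was made stricter after the value was seen. The reason was that the first bound would have ruled it out only narrowly. Differentiation, X inactivation and loss of an X in some cells stay open and were not tested.

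Allele calls repeated in part: CLIP pairs had one allele in 59.0% to 69.4% of cases on chromosome 13, past a Fisher exact test with Benjamini-Hochberg adjustment in 6 of 6 pairs, and in 52.6% to 67.1% on X, in 2 of 6. For ChIP these were 57.8% to 63.7% and 56.9% to 66.7%, in 1 of 3 pairs each. Weak peaks as the cause of disagreement cannot be told apart: the odds ratio of agreement for higher against lower scores was 1.09 over both assays (Fisher exact p = 0.330), which joins 1.29 for CLIP (63.1% against 56.9%, Fisher exact p = 0.0152) and 0.724 for ChIP (58.0% against 65.6%, Fisher exact p = 0.0585). These counts reuse libraries; in the 3 sets of CLIP pairs that share none the odds ratio was 1.07, 1.27 and 1.60, and 1 of them passed (Fisher exact p = 0.0127), while single ChIP pairs ranged from 0.509 to 1.07, and 1 of them passed in the other direction (0.509, Fisher exact p = 0.0370). No biological explanation was tested.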

How the results depend on the processing

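Replicate overlap, the X odds ratio and the overlap of CLIP with ChIP kept their direction and passed under all alternatives run, except the day 3 X odds ratio with FPKM of at least 0.1 (1.14, Fisher exact p = 0.0518); the cause was not tested. Bound regions numbered 14131 at day 0 and 13813 at day 3 with a peak in either replicate, a looser rule by construction. The day 0 sense share was 98.4% for peaks with above-median scores and 98.5% in regions with FPKM of at least 1. limma called 0 regions in all settings run, with 645 to 1330 at an unadjusted p under 0.05; without one library, the lone library of a day was assumed to vary like the others. With the replicate block it called 0, with 1252 at that p. Deviations of replicate 1 from replicate 2 in scaled peak bases did not correlate between days (correlation 0.0178). The lists still differed by replicate number at both days. The lowest score was 409 at day 0 and 406 at day 3 in replicate 1, and 221 and 212 in replicate 2. Median peak lengths were 46 and 47 bp against 38 and 36 bp. The correlation of scaled values therefore cannot show that samples were unpaired. The share of day 3 ChIP peaks found at day 0 was 87.5% with 50% overlap, 97.8% for above-median scores, 88.7% within 500 bp, and 68.9% to 86.7% without either day 0 library. Without ChIP day 0 replicate 1 the day 0 CLIP over ChIP fold was 1.85, and without replicate 2 it was 1.07. CLIP alleles changed sign by strand with no call behind them: plus alone 1.02 in day 0 replicate 1, minus alone 0.886 in day 0 replicate 2 and 0.954 in day 3 replicate 1. Plus alone passed without correction in day 0 replicate 2 (1.18, Fisher exact p = 0.0264) and day 3 replicate 1 (1.35, Fisher exact p = 0.00572). In both libraries the chromosome 13 reference differed more by strand than X did. In day 3 replicate 1 it was 44.5% cas on plus and 53.9% on minus, against 52.0% and 52.7% on X. Why the reference differed was not tested. RNA-seq regions of at least 300 bp numbered 7016 higher and 12488 lower at day 3 with no FPKM filter, and 6853 and 11819 with mean FPKM of at least 1, which turns the balance. More regions were listed at day 0 alone (15687) than at day 3 alone (4166), and each was set to 0 at the other day. Lower filters let more of these in, but their part in the turn was not counted. In the single-transcript set, chosen after seeing the data, 1666 were higher and 349 lower, with fewer regions by construction. Among regions listed at both days, also chosen after seeing the data, 4157 were higher and 2132 lower, since regions missing at either day are left out. Limiting alleles to peaks of the full list changed nothing by construction. Gene-list, X-inactivation centre and motif alternatives were not run. Read depth is unknown and limits all lists.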
